A study of Mus musculus with 2 samples.

How the data were processed

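ATAC-seq libraries of heart tissue from mouse embryos at 11.5 days (strain B6NCrl, both sexes pooled) were analysed, 2 biological replicates of 1 group. Replicate 1 was pooled from 162 embryos, per the labels, and both replicates carry the same donor label. The labels call them biological replicates and say no more on how separate the 2 pools of embryos were, so the spread between them may be partly technical. The authors deposited peak lists, and per the README deposited with the files each was derived from alignments to mm10. The aligner, the peak caller, the shift of reads for the transposase and all versions are not given in the sources used here. The lists give no read totals, so the depth of each library is unknown and no value could be adjusted for it.

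For each replicate the authors deposited a ranked list, a thresholded list and a looser list of peaks supported by pseudoreplicates, per the output types named in the README. Pseudoreplicates are, in general use, made by a random split of the reads of a library. For both libraries pooled they deposited the same kinds of list, a conservative thresholded list made from a comparison of the replicates and a looser list of peaks replicated in both. Column 7 of each list holds the fold enrichment of the summit over the local background, a linear ratio that the authors' peak caller gave. Column 8 holds the −log10 of the p-value, which the authors' caller gave and which depends on depth. Column 5 of the ranked and thresholded lists holds a score that the authors scaled from the irreproducible discovery rate (IDR), a measure of how well a peak's rank repeats. The lowest score in the thresholded lists was 540, an IDR of 0.0501, so the authors' threshold was read from the deposited values as 0.05. Each thresholded list was tested against its ranked list: all of its entries were there, and summits past the threshold that were not in the thresholded list are counted in the closing section. The pooled thresholded list matched the ranked list of pseudoreplicates and the conservative list the ranked list that compares the replicates.

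Overlapping or touching intervals of a list on chromosomes 1 to 19, X and Y were merged into regions, and the summit with the highest fold stood for the region. No region reached beyond the end of its GRCm38 chromosome. Protein-coding genes, their starts and their exons were taken from GENCODE release M21 and the sequence from GRCm38 patch 6. Noncoding genes were left out, so a summit inside one was called intergenic unless it lay at a promoter or in a protein-coding gene. A region was a promoter region when its nearest edge lay within 1 kb of a start of a protein-coding transcript and distal otherwise, while the 4 genomic classes were read at the summit; a distal region was given to the gene with the nearest start within 100 kb. A region counted as shared when it overlapped a region of the other list by at least 50% of the shorter one, and 100 random placements within chromosomes gave the chance level. Coordinates are printed counting from 1.

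The design, the 16 gene lists, the 22 consensus sequences and the alternatives were fixed before the data were examined, except where the closing section says otherwise. All members of the 16 lists were found in the annotation. Each list was described by its percentile among 10000 random lists of the same size, matched on decile of the GC content of the 1 kb around the start (promoters) or on decile of the length of sequence nearest to the gene (distal regions). A list was said to stand apart above the 95th or below the 5th percentile. With 1 group of 2 replicates no test between samples was possible, and no p-value was computed across genes or regions. Means over replicates are given with the SD (n = 2), which is the spread between the 2 libraries. Shares are given with exact Clopper-Pearson 95% intervals and ratios of shares with 95% intervals on the log scale. Both kinds of interval cover counting error only. Consensus sequences were counted on either strand within 50 bp of the summit and in equal windows 500 bp to either side that lay in no region of the list.

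The genes named were chosen by a rule. It takes 2 to 4 members per list (those with the most distal regions, ties by the higher fold of the strongest region, and for lists mostly without promoter regions the members that have one) and any other list member beside its list's count. It also takes the 15 genes with the most distal regions, the 10 distal regions and the 5 promoter regions with the highest fold. The alternatives were other overlap rules, an IDR of 0.01, the conservative, replicated and looser lists, promoter distances of 500 bp and 2 kb, a limit of 50 kb, no matching, motif windows of 100 bp either side, the reversed consensus and each replicate alone.

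For the closing section, sequences of chosen regions were searched with blastn 2.17.0 (megablast, word size 28, no filter on simple sequence, E value 1e-10, identity of at least 90%). A region counted as matched when matches to the mitochondrial genome covered at least 50% of it, or when another place in the nuclear genome matched at least 50% of it. These search rules were settled over several runs. A shorter word size ran too long to give a result. The first search used all sequences of the assembly, and alternate loci and patches were then left out because they repeat places of the chromosomes, a choice made after the first counts were seen. It changed the regions with a nuclear copy from 5 to 2 of 6 globin promoters, from 7 to 4 of 7 regions near Tex14, from 7 to 3 of 100 random distal regions and from 48 to 47 of 84 regions left out of the thresholded list. The 10 strongest distal regions (5) and the 15 regions near Sfi1 (15) kept their counts.

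The scripts ran on Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9. The functions were tested on simulated data first. Of 2000 simulated regions, 60.1% were made to be shared and 60.1% were recovered. Of 300 random gene lists, 6.33% fell outside the 5th to 95th percentile, and of 100 lists planted with open promoters, 100% lay above the 95th.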

Results

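Accessible chromatin was profiled by ATAC-seq, in which a transposase cuts and tags DNA that is not covered by nucleosomes, in hearts of mouse embryos at 11.5 days of development. The 2 libraries were biological replicates of 1 group, healthy B6NCrl hearts pooled over both sexes, and replicate 1 was pooled from 162 embryos. The series held no second tissue, age or treatment, so no comparison between groups could be made. The values were lists of accessible regions called on each library and on both libraries pooled, in mm10 (GRCm38) coordinates. After overlapping intervals of a list were merged, replicate 1 gave 13331 regions over 10.4 Mb with a median width of 772 bp. Replicate 2 gave 10751 regions over 8.09 Mb with a median width of 739 bp. The pooled list gave 16011 regions over 13.2 Mb with a median width of 810 bp, built from 36792 summits. The read depth of the libraries is unknown, since the lists give no read totals, and the intervals quoted for shares cover counting error only. The fold enrichment of a region is the authors' own value over the local background and is used only within its list.

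Promoter regions made up most of the pooled thresholded list. Of the 16011 pooled regions, 10704 lay within 1 kb of a protein-coding start, a share of 66.9%. The same lengths placed at random reached 3.63%, so promoters were 18.4 times as frequent as by chance. The promoters with the highest folds were those of Tmem218, a membrane protein gene, at 21.2, Fopnl at 20.7, Kifap3, which encodes a kinesin-associated protein, at 20.5, Cfdp1 at 19.9 and Tmem126b, a factor in assembly of the respiratory chain, at 19.8. Each of the 5 was also found in both replicates, with replicate folds from 16.6 to 22.7. These regions lay over the annotated start itself, for example chromosome 9, 37207916 to 37208626, for Tmem218 and chromosome 16, 14316848 to 14317846, for Fopnl. By the class at the summit, 65.8% of pooled regions were promoter, 1.89% exon, 14.3% intron and 18% intergenic, against 2.67%, 3.28%, 36.3% and 57.8% in random placements. Exons and introns were those of protein-coding genes only, so intergenic sequence here can include noncoding genes. The share within 1 kb of a start was 72.3% in replicate 1 and 78.3% in replicate 2 (75.3% ± 4.20, SD, n = 2), both above the pooled value. Exon and intron shares were lowest in replicate 2, at 1.18% and 8.48%. In the looser list of regions seen in both replicates, the share within 1 kb of a start was 38.0%, so promoter regions were not the majority there.

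**Figure D1:**
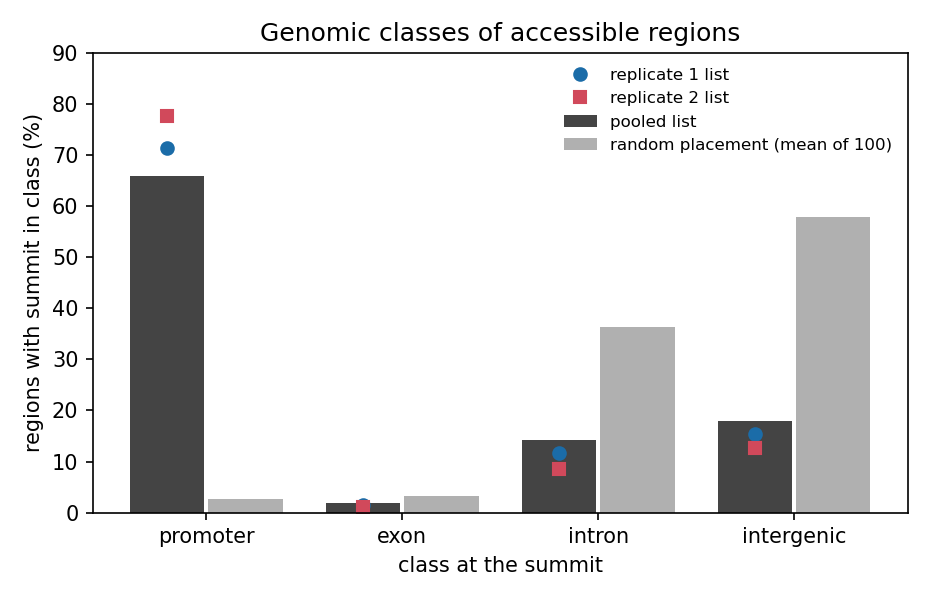
Share of regions (%) whose summit lay in a promoter (within 1 kb of a protein-coding start), an exon or intron of a protein-coding gene, or intergenic sequence outside all of these. Dark bars show the pooled list, points the lists of the 2 replicates and light bars the mean of 100 random placements; promoters took 65.8% of pooled regions against 2.67% at random, and the other 3 classes lay under their random shares.

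Distal regions, more than 1 kb from every protein-coding start, were narrower and weaker than promoter regions. The 5307 distal regions had a median width of 527 bp and a median fold of 5.50, against 936 bp and 8.19 for the 10704 promoter regions. Their median distance to the nearest start was 21.8 kb, and 13.9% lay beyond 100 kb. In the replicate lists the same order held, with median folds of 6.25 for distal and 8.59 for promoter regions in replicate 1, and 6.50 and 8.34 in replicate 2.

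At the level of genes, 10996 of 21853 protein-coding genes (50.3%, exact 95% interval 49.7 to 51.0) had a region at a promoter in the pooled list, 10049 in replicate 1 and 8954 in replicate 2. Genes of the X chromosome had one less often than autosomal genes, at 35.9% of 948 (32.8 to 39.0) against 51.4% of 20722 (50.7 to 52.1). Of the 183 genes of the Y chromosome, 2 had one. These shares by chromosome were not matched on the GC content of the promoters. Olfactory receptor genes, which encode odorant receptors of the nose, almost all lacked a promoter region, with 4 of 1134 carrying one. The share rose with the GC content of the promoter, from 2.61% in the lowest decile of genes to 80.7% in the highest. Gene lists were therefore set against random lists matched on this GC content.

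The promoters of heart muscle genes were mostly accessible in the pooled list. Of the 25 sarcomere and contraction genes, 18 had a promoter region, against a mean of 52.9% in matched random lists (percentile 98.1 of 10000 lists). Among the members with the most distal regions, Myl3, a myosin light chain of slow muscle and ventricle, had a promoter fold of 3.77, and Ryr2, the calcium release channel of the cardiac sarcoplasmic reticulum, had 4.77. Myl2, the ventricular regulatory light chain, had no promoter region in the pooled list and had one in replicate 1, with a fold of 4.22. Myh7, Nppa, Pln, Myoz2 and Nebl had none in the pooled list or in either replicate. The atrial light chain gene Myl4 had a fold of 10.3, and Myh6, the alpha myosin heavy chain, had 3.37 and passed in neither replicate alone. Of the 18 promoters, 8 were found in both replicates. In replicate 1 alone, the list fell to the 80.3 percentile, with 14 open promoters. In replicate 2 alone it fell to the 24.5 percentile, with 9, and with the stricter threshold of 0.01 for the irreproducible discovery rate it fell to the 21.2 percentile.

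The cardiac transcription factors had 19 of 25 promoters accessible, against 67.5% in matched lists (percentile 83.8), and 16 of these were found in both replicates. Mef2c, which drives muscle gene expression, had a promoter fold of 4.66, Hand2, a basic helix-loop-helix factor of the right ventricle, 4.71, and Hey1, a Notch target of the atrium, 8.39. Nkx2-5, an early cardiac homeobox gene, had 6.93, and Tbx5, Tbx2, Hand1, Irx4, Smarcd3 and Prdm16 had no promoter region in the pooled list. Of the conduction and ion channel genes, 7 of 16 had one (percentile 17.5), among them Cacna1c, the L-type calcium channel, with a fold of 7.64, Gja5, the connexin of fast-conducting tissue, with 10.3, and Kcnh2, a repolarizing potassium channel, with 5.51. Of the endocardial and endothelial genes, 13 of 24 had one (percentile 36.7), including Nfatc1, a marker of endocardium, with a fold of 6.01, Kdr, a receptor for vascular endothelial growth factor, with 6.06, Notch1 with 6.02 and Tek, an angiopoietin receptor, with 4.54. In the lists of single replicates the endothelial genes stood lower, at the 2.44 percentile in replicate 1 and the 3.39 percentile in replicate 2. In the looser list of regions seen in both replicates, these 3 lists moved up, to the 99.92, 98.6 and 99.5 percentiles.

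Of the other heart lists, the one of the second heart field and outflow tract stood below its matched lists. Of the 15 epicardial genes, 6 had a promoter region, against 56.4% in matched lists (percentile 9.16). They were Wt1, a zinc finger factor of the epicardium, with a fold of 3.84, Sema3d with 6.91, Tbx18 with 5.04, Upk1b, Krt8 and Upk3b. Of these, Sema3d alone was found in both replicates, and the list fell to the 0.465 percentile in replicate 1 and the 0.045 percentile in replicate 2. Of the 20 cushion and valve mesenchyme genes, 9 had one (percentile 38.2), among them Col1a2, a fibrillar collagen chain, with 5.30, Snai1, a driver of the change from epithelium to mesenchyme, with 7.53, and Msx2 with 6.66. That list reached the 8.18 percentile in replicate 1 and the 0.805 percentile in replicate 2. Of the 15 genes of the second heart field and outflow tract smooth muscle, 3 had one, against 52.7% in matched lists (percentile 0.270): Eya1, a transcriptional coactivator, with 7.29, Foxc1, a forkhead factor, with 6.36, and Sema3c, a guidance signal for outflow tract cells, with 7.26. Smooth muscle genes of that list, Acta2, Tagln, Cnn1 and Myh11, had no promoter region. Its percentile was 30.3 in the authors' conservative list and 73.4 in the looser list of regions seen in both replicates.

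Promoters of genes that mark other organs mostly had no region past the threshold. A promoter without one is not shown to be closed, since sarcomere genes such as Nppa and Myh7 had none either. None of the 18 skeletal muscle genes, 20 lung, gut and other endoderm genes or 17 limb and distal Hox genes had a promoter region in the pooled list or in either replicate, against 46.1%, 56.4% and 70.0% in their matched lists. Myod1, which commits cells to skeletal muscle, was among them. Of the liver genes, 2 of 18 had one, Foxa3 with a fold of 8.32 and Prox1 with 5.47. The secreted proteins Alb and Afp had none. The Foxa3 region (chromosome 7, 19024025 to 19025143) lay wholly outside the gene (19013284 to 19023538) and counted by the 1 kb rule. That rule does not tell whether such a region belongs to a neighbouring gene. Of the neural genes, 5 of 25 had a promoter region. Among them were Syt1, a synaptic vesicle protein, with a fold of 9.94, Elavl4 with 8.07, Foxg1 with 5.45 and Snap25 with 3.76. Of the germ cell and pluripotency genes, 1 of 18 had one, Dazl, an RNA-binding protein of germ cells, with 8.44. The percentile of each of these 6 lists lay at 0.160 or lower, and that of the neural list rose to 16.7 in the looser list of regions seen in both replicates. At the other end, all 24 housekeeping genes and all 24 cell cycle genes had a promoter region. The housekeeping genes Actb and Ywhaz had folds of 6.82 and 8.45, and the proliferation genes Mki67 and Aurkb had 10.4 and 4.4. Their matched lists averaged 69.9% and 66.2%. In all, 4 of the 16 lists lay above the 95th percentile, 7 below the 5th and 5 between. No p-value was computed, since genes of 1 pool of libraries are not replicates.

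**Figure D2:**
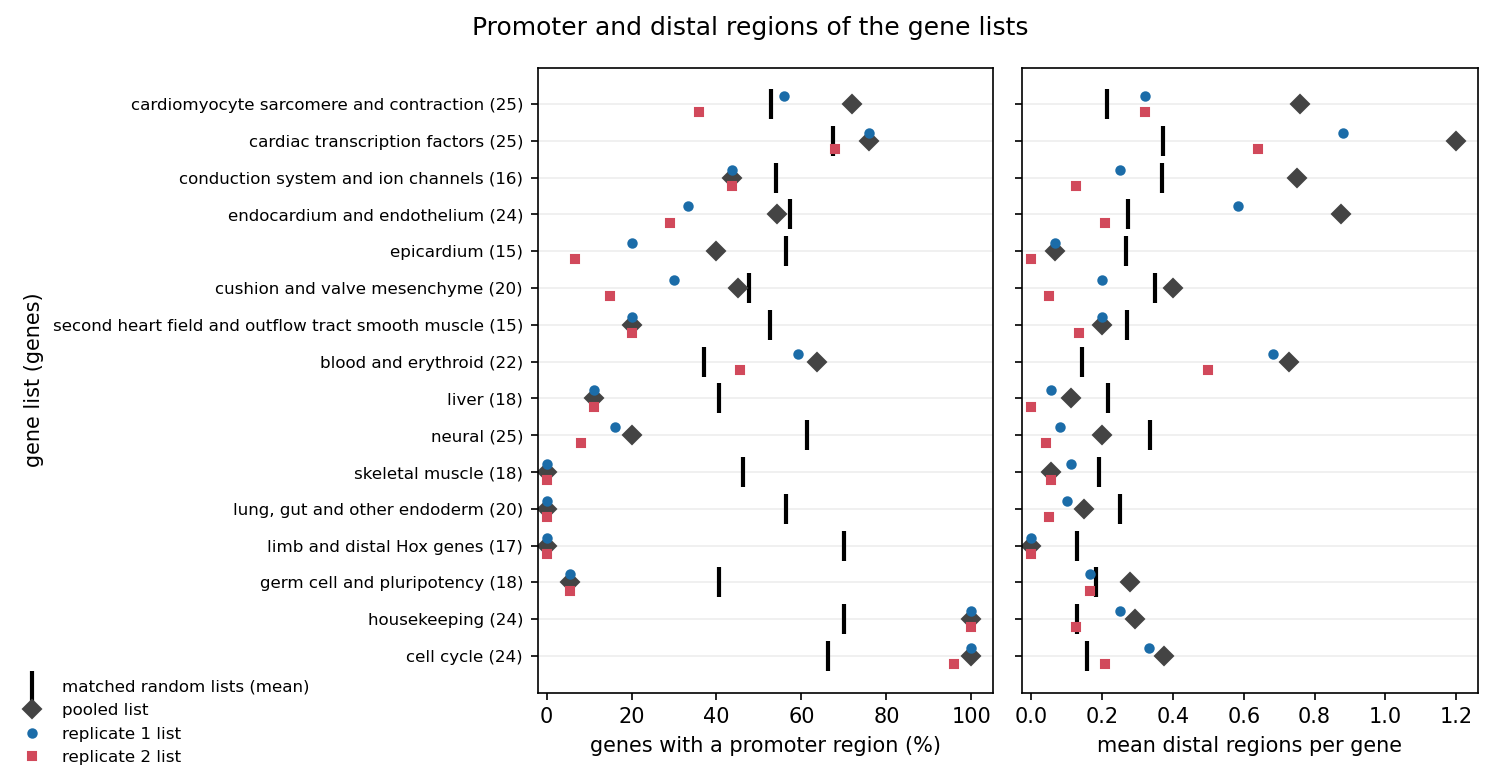
Left, share of each list's genes (%) with a region at a promoter; right, mean number of distal regions per gene with the nearest start within 100 kb. Diamonds show the pooled list, circles and squares replicates 1 and 2, and black ticks the mean of 10000 matched random lists; the cell cycle and housekeeping lists sit at 100% on the left, and the cardiac transcription factors have the highest distal mean, 1.2.

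The lists past the 95th percentile of their matched lists for distal regions were those of cardiac transcription factors, sarcomere, endothelium, blood and cell cycle. The cardiac transcription factors had a mean of 1.2 distal regions per gene, against 0.371 in random lists matched on the length of sequence nearest to each gene (percentile 99.985). The replicate lists gave 0.880 and 0.640 (0.760 ± 0.170, SD, n = 2). Mef2c had 5 distal regions, the strongest with a fold of 6.79 in an intron of the gene, 4.76 kb from the nearest start (chromosome 13, 83517734 to 83518712). Hand2 had 4, the strongest with 7.31 in intergenic sequence 32.4 kb from its start (chromosome 8, 57353432 to 57354264), and Hey1 had 3, the strongest with 8.18 at 17.5 kb (chromosome 3, 8684794 to 8685646, intergenic). The sarcomere genes had a mean of 0.760 against 0.213 (percentile 99.9). Myl2 had 3 distal regions, and its strongest, with a fold of 5.70, lay 16.2 kb away in intergenic sequence (chromosome 5, 122084545 to 122084783). Myl3 had 2, the strongest with 7.96 in an intron of the neighbouring Pth1r, 8.89 kb from the Myl3 start (chromosome 9, 110732480 to 110732974). Ryr2 had 2, the strongest with 5.67 at 26.5 kb (chromosome 13, 12133449 to 12134285, intergenic). The sarcomere mean was 0.320 in each replicate list, which placed it at the 99.2 percentile in replicate 2 and the 94.5 percentile in replicate 1.

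The endocardial and endothelial genes had a mean of 0.875 distal regions against 0.273 (percentile 99.9). Nfatc1 had 3, the strongest with a fold of 5.69 in its own intron 82.4 kb from the nearest start (chromosome 18, 80624962 to 80625737). Kdr had 2, the strongest with 6.45 at an exon, 15.9 kb from the start (chromosome 5, 75962177 to 75962582), and Tek had 2, the strongest with 5.12 in an intron at 12.9 kb (chromosome 4, 94752427 to 94752930). This mean was 0.583 in replicate 1 and 0.208 in replicate 2 (0.396 ± 0.265, SD, n = 2), and in replicate 2 alone the list fell to the 84.9 percentile. The conduction and ion channel genes had 0.750 against 0.369, at the 94.9 percentile, with 2 regions each near Cacna1c, Gja5, Kcnh2, Kcnj5 and the cardiac sodium channel gene Scn5a. The mean of this list was much lower in the replicate lists, at 0.250 and 0.125 (0.188 ± 0.0884, SD, n = 2). The cell cycle genes had 0.375 against 0.157 (percentile 96.3), with 3 regions each near Mki67 and Aurkb, and the share of these genes with a distal region stood at the 78.2 percentile. The housekeeping genes had 0.292 against 0.129 (percentile 94.7), which rose to the 96.4 percentile in replicate 1. The cushion list had 0.4 against 0.349 (percentile 65.4), with 2 regions near Col1a2. Between the 5th and 95th percentiles also lay the epicardial list (0.0667, percentile 10.5), with 1 region near Wt1, the second heart field and outflow list (0.2, percentile 39.6), liver (0.111, percentile 25.9), neural (0.2, percentile 20.1) and skeletal muscle (0.0556, percentile 14). Endoderm had 0.15 (percentile 27.0), limb and distal Hox genes 0 (percentile 8.50) and germ cell genes 0.278 (percentile 79.4). In all, 5 lists lay above the 95th percentile and none of the 16 below the 5th. With the stricter threshold, 2 lists lay above, and the sarcomere, endothelial and cell cycle lists fell to the 88.9, 93.2 and 91.7 percentiles.

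Blood genes were accessible in these hearts. Of the 22 blood and erythroid genes, 14 had a promoter region, against 37.1% in matched lists (percentile 99.6), 13 in replicate 1 and 10 in replicate 2. All 6 globin genes of the list were among them. The adult beta-globin gene Hbb-bt had a promoter fold of 8.66, the embryonic genes Hbb-bh1 and Hbb-y had 7.58 and 6.42, the embryonic alpha-like gene Hba-x had 5.83, and Hba-a1 and Hba-a2 had 4.44 and 5.81. The regions of Hba-a1 and Hba-a2 each had a copy elsewhere in the genome at 100% identity, over at least 50% of the region. The erythroid factors Gata1, Klf1 and Nfe2 had 6.86, 5.70 and 10.9, and Runx1, a factor of blood stem cells, had 9.52. The white blood cell genes Ptprc, Spi1, Csf1r, Cd68 and Cx3cr1 and the platelet gene Pf4 had none, while Itga2b, another platelet gene, had a promoter fold of 4.77. Without the 6 globin genes, a setting chosen after seeing the data, 8 of 16 were open and the list stood at the 80.6 percentile, and for distal regions at the 99.8 percentile, with a mean of 0.75 against 0.179. Against random lists with no matching on GC content, all 22 genes stood at the 89.2 percentile. The list had a mean of 0.727 distal regions per gene, against 0.142 in matched lists (percentile 100), and 0.682 and 0.5 in the replicates (0.591 ± 0.129, SD, n = 2). Hbb-y had 4 distal regions, the strongest with a fold of 10.3 in intergenic sequence 5.94 kb from its start (chromosome 7, 103859152 to 103859497). Runx1 had 2, the strongest with 10.0 at 57.6 kb (chromosome 16, 92883739 to 92884292, intergenic), and Alas2, the first enzyme of heme synthesis in red cells, had 2, the strongest with 8.98 in its intron (chromosome X, 150549561 to 150550076), 2.1 kb from the nearest start.

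**Figure D3:**
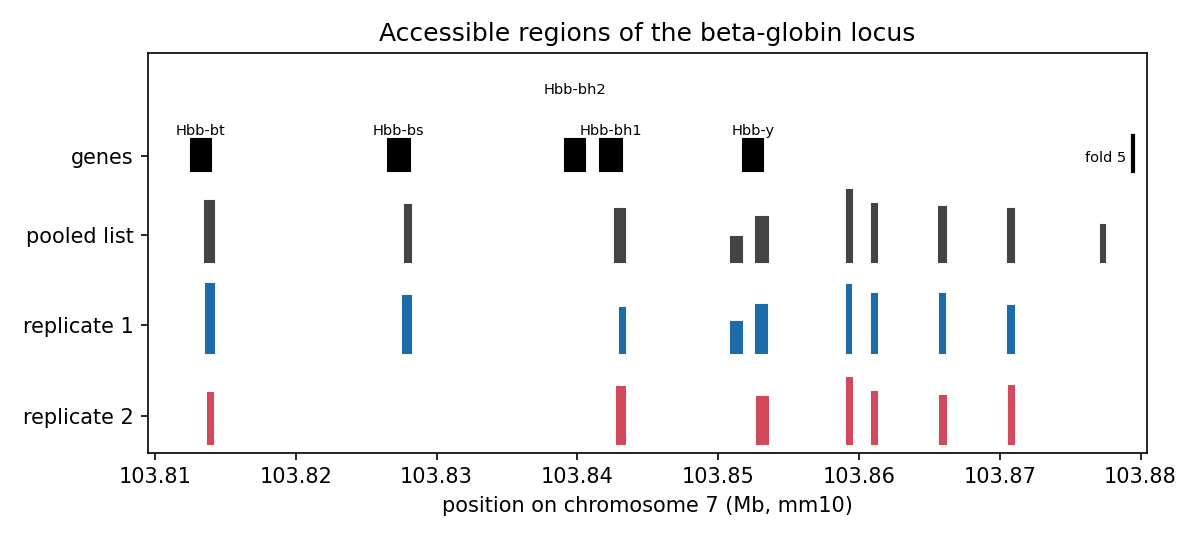
Map of the beta-globin locus on chromosome 7 (mm10, position in Mb) with the annotated globin genes and the regions of the pooled list and of replicates 1 and 2; bar height is proportional to the authors' fold. Regions lie over the starts of Hbb-bt and Hbb-y in each of the 3 lists, and the strongest distal region of the locus, at 103859152 to 103859497, has a pooled fold of 10.3.

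The 15 genes with the most distal regions by nearest start ranged from 15 regions to 6. Sfi1, a centrosome gene on chromosome 11, had 15, the strongest with a fold of 4.32, and each of the 15 had a copy elsewhere in the genome. It was followed by Gm21860 on the Y chromosome with 8, of which 6 had copies, Fcgr3, an immunoglobulin receptor of white blood cells, with 8, of which 7 had copies, and Acot11, an acyl-CoA thioesterase, with 8, none with a copy. Next came Cpeb4, a regulator of translation, Tex14 and Slc20a1, a phosphate transporter, with 7 each, 4 of the Tex14 regions having copies. Chd7, a chromatin remodeller needed for heart and outflow tract development, had 6 regions, as had Ier5, Trim27, Actg1, Ank3, Smad6, an inhibitor of bone morphogenetic protein signalling in heart valves, Usp29 and Gse1. None of these had copies except 2 regions near Usp29. The strongest of these regions without regard to copies were near Cpeb4, with a fold of 14.5 in intergenic sequence 1.17 kb from the start (chromosome 11, 31870261 to 31871040), in an intron of Tex14, with 14.4 (chromosome 11, 87442649 to 87443823), and near Chd7, with 12.2 at 42.7 kb (chromosome 4, 8647043 to 8647761, intergenic). Smad6 had its strongest region 22.9 kb away, with a fold of 8.22 (chromosome 9, 64044963 to 64045755, intergenic). Of the 15 genes, Sfi1, Gm21860 and Cpeb4 had no promoter region. Counts in the replicate lists were mostly lower, for example 6 and 6 for Sfi1, 5 and 5 for Cpeb4, 2 and 1 for Chd7 and 3 and 1 for Ank3. Sfi1 did not lead these 15 genes alone there, since Tex14 and Gse1 also had 6 in replicate 1 and Gm21860 had 6 in replicate 2.

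In the pooled thresholded list, the 10 strongest distal regions had higher folds than any promoter region. All 10 were intergenic, and all 10 were found in both replicates. The strongest, with folds of 55.7 in the pooled list, 51.6 in replicate 1 and 55.6 in replicate 2, lay 12.9 kb from Abcb11, a bile salt transporter gene (chromosome 2, 69355469 to 69355735), and 48.3% of its length matched the mitochondrial genome at 100% identity. The next lay 35.4 kb from Pak3, with 55.2 (chromosome X, 143482936 to 143483180). Those nearest Gm5426 with 47.4 (chromosome 10, 96077546 to 96077952, 58.7 kb away), G6pd2 with 43.4 (chromosome 5, 60042692 to 60043140), Tyrp1 with 30.5 (chromosome 4, 80002694 to 80003058), Galc with 29.4 (chromosome 12, 97061368 to 97061856) and Nxph1 with 28 (chromosome 6, 9889881 to 9890224) matched the mitochondrial genome over at least 50% of their length. The nearest starts of the last 4 were between 831 and 1766 kb away. The remaining 3 lay 53.1 kb from Frmd4a with a fold of 38.3 (chromosome 2, 3964426 to 3964690), 14.6 kb from Myl12b with 30.0 (chromosome 17, 70963584 to 70963965) and 11 kb from Hic2 with 26.7 (chromosome 16, 17222196 to 17222580). Copies elsewhere in the nuclear genome were found for the regions nearest G6pd2, Tyrp1, Myl12b, Galc and Nxph1.

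Binding sequences of GATA factors, which include the heart regulators Gata4, Gata5 and Gata6 and the erythroid factor Gata1, were frequent at distal summits. A GATA consensus lay within 50 bp of 17.6% of distal summits, against 5.57% of flanking windows, a ratio of 3.16 (95% counting interval 2.85 to 3.51). The replicate lists gave 3.32 and 3.55 (3.44 ± 0.167, SD, n = 2). The reversed sequence had 0.492 (0.406 to 0.596), so GATA divided by it stood at 6.43. The consensus of CTCF, which organizes chromatin loops, had a distal ratio of 9.51 (5.51 to 16.4), RFX 9.22 (3.19 to 26.6) and SP and KLF 8.79 (6.14 to 12.6), and their order differed between lists. In replicates 1 and 2, CTCF had 4.75 and 8.20, RFX 8.27 and 6.79, and SP and KLF 7.09 and 8.34. NFY lay at 5.05 (3.89 to 6.57) and AP-1 at 3.55 (2.91 to 4.33). Among the consensus sequences of other heart factors, SRF, which controls muscle genes, had a ratio of 2.02 (1.22 to 3.34), T-box factors 1.81 (1.4 to 2.33), where the reversed sequence gave nearly the same, 1.69 (1.35 to 2.1), MEIS 1.78 (1.60 to 1.98) and TEAD 1.5 (1.25 to 1.80). In replicates 1 and 2, SRF had 1.59 (0.908 to 2.78) and 1.51 (0.771 to 2.95), whose intervals held 1, and TEAD had 1.35 (1.06 to 1.71) and 1.25 (0.924 to 1.68), of which the second did. The E-box of HAND factors had 1.12 (0.998 to 1.26) and MEF2 had 0.861 (0.638 to 1.16), whose intervals held 1, and NKX2 had 0.691 (0.552 to 0.865). The reversed HAND sequence had 0.602 (0.489 to 0.741), so HAND divided by it stood at 1.86. The reversed MEF2 sequence was much rarer at distal summits than beside them, at 0.0354, so MEF2 divided by it stood at 24.4 (7.47 to 79.4). The ETS consensus of endothelial and blood factors had 1.90 (1.59 to 2.28). The MYOD E-box, named here for skeletal muscle factors, lay at 12.4% of distal summits, with a ratio of 2.60 (2.31 to 2.93) and 2.46 and 2.56 in the replicates. Its reversed sequence gave 1.76 (0.749 to 4.15), an interval that holds both 1 and 2.60, so this control decides nothing for it. Divided by the reversed sequence, it stood at 1.48. With CTCF, SP and KLF, and NFY also above, the sequences above their flanks were not those of heart factors alone.

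At promoter summits, most of the sequences above their flanks were also above them at distal summits. The ETS consensus had a ratio of 3.77 (3.31 to 4.30), SP and KLF 21.4 (17 to 27.0), NFY 15.8 (12.7 to 19.7), RFX 9.89 (3.02 to 32.3) and CTCF 3.98 (2.17 to 7.28). The NRF1 consensus, of a factor for mitochondrial and growth genes, lay at 1.12% of promoter summits and 0.00976% of flanks, a ratio of 115 whose interval ran from 16.1 to 822. Replicate ratios for NRF1 were 56.4 and 38.9, those for CTCF 2.31 and 1.74 and those for RFX 16.1 and 11.2. The GATA consensus was rarer at promoter summits than beside them, with a ratio of 0.316 (0.265 to 0.376), and the reversed sequence gave nearly the same, 0.324. In all, 12 of 21 consensus sequences lay above their flanks at distal summits and 7 of 21 at promoter summits. Below their flanks lay 2 of 21 at distal and 9 of 21 at promoter summits, and 0 of 19 and 2 of 20 after division by the reversed sequence. The counts above were 11 of 21 and 7 of 21 in replicate 1 alone, and 10 of 20 and 5 of 21 in replicate 2 alone. HNF1 matches were too rare for a ratio. Divided by the ratio of the reversed sequence, NKX2 at distal summits and MEF2 at promoters turned from below to above, at 1.70 and 7.46. The MYOD E-box at promoters turned from above to below, at 0.375. The reversed sequences themselves departed from their flanks there, at 0.406, 0.0145 and 3.39 (2.19 to 5.23), in the same order. The reversed MYOD E-box, GTCGAC, holds a CG pair that CAGCTG lacks. This control thus differs in makeup from the E-box, and the turn decides nothing for it.

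**Figure D4:**
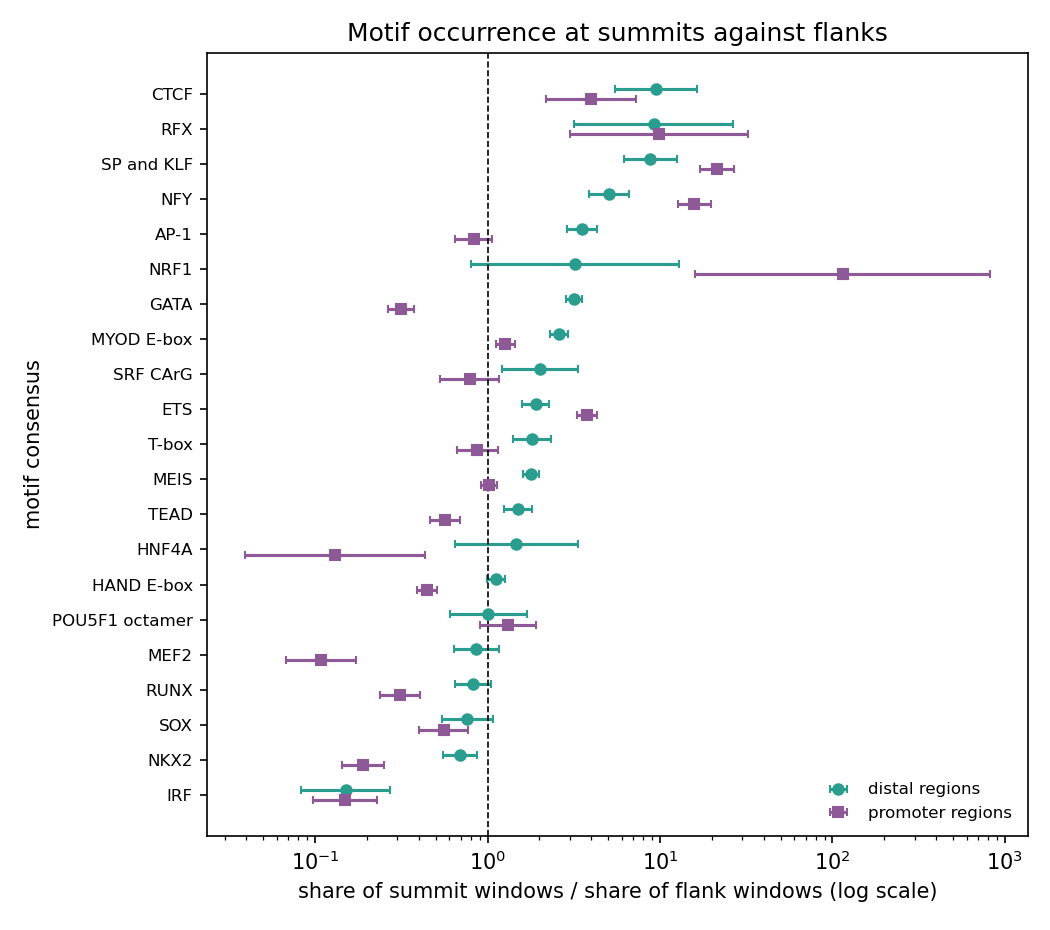
Share of summit windows with a consensus match divided by the share of flanking windows (log scale), for distal (circles) and promoter (squares) regions of the pooled list, with 95% counting intervals; the dashed line marks equal shares. CTCF lies at 9.51 in distal regions and NRF1 at 115 in promoters, and GATA lies at 3.16 in distal and 0.316 in promoter regions.

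The replicates shared most of their regions. Of the regions of replicate 1, 73.5% (exact 95% interval 72.7 to 74.2) overlapped a region of replicate 2 by at least 50% of the shorter one, and 91.6% (91.1 to 92.1) of the regions of replicate 2 overlapped one of replicate 1. Random placements of the other list reached 0.418% and 0.521% on average. Promoter regions were shared more often than distal regions, at 82.5% against 49.9% in replicate 1 and 95.1% against 79.0% in replicate 2. Among promoters, those of the factor genes Hey2 and Tbx20 had folds of 14 and 10.7 in the pooled list and were found in both replicates. The promoters of Wt1 and Tnnc1, with 3.84 and 3.11, passed in neither replicate alone. Sharing rose with the fold, from 30.1% in the lowest decile of replicate 1 to 99.8% in the highest, and from 71.8% to 100% in replicate 2. Of the 3539 regions of replicate 1 and the 900 of replicate 2 that were not shared, 85.4% and 89.9% were present in the looser list of the other replicate. Across the 74271 summits that the authors ranked in both replicates, the Spearman correlation of the −log10 p values was 0.685. Of the first intervals compared, 64.6% were also in the ranked list of replicate 1 and 0.0913% in that of replicate 2, and of the second 0.105% and 55.0%, so the ranking covers intervals that those lists do not hold. Summits are not independent replicates, so no p-value is given for it.

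**Figure D5:**
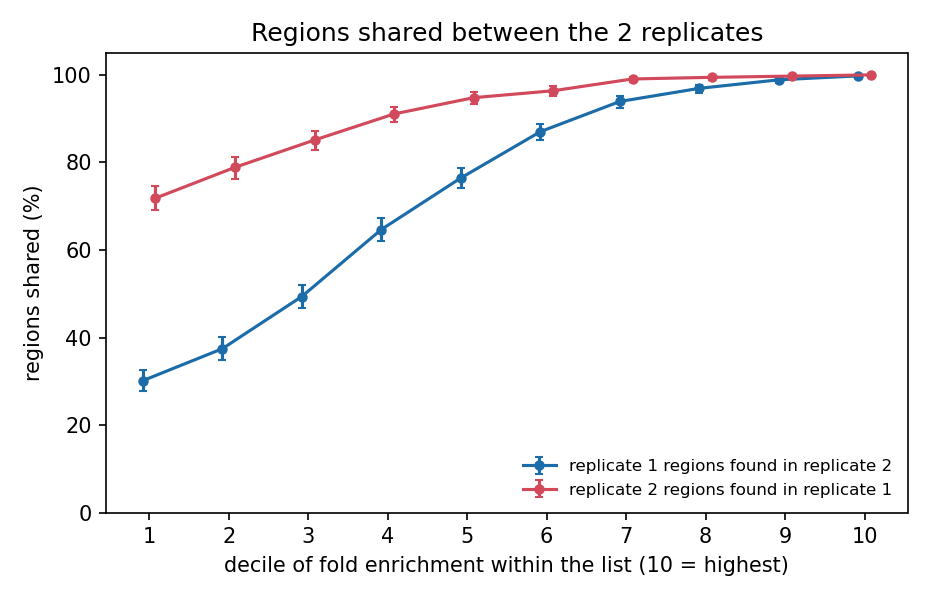
Share of the regions of each replicate (%) found in the other, by decile of the authors' fold within the list, with exact 95% intervals that cover counting error only. The share rises from 30.1% to 99.8% for replicate 1 and from 71.8% to 100% for replicate 2.

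Of the 16011 pooled regions, 60.4% were found in both replicates, 18.6% in replicate 1 alone, 4.74% in replicate 2 alone and 16.2% in neither. The median pooled fold fell in the same order of support, from 9.04 for regions in both replicates to 5.43 and 5.59 for those in replicate 1 or 2 alone and 4.44 for those in neither. Of the blood and erythroid genes with a pooled promoter region, 9 of 14 had one in both replicates, of the cardiac transcription factors 16 of 19, of the endothelial genes 5 of 13, of the cell cycle genes 23 of 24 and of the housekeeping genes 24 of 24. The conservative list, which the authors built by comparing the replicates, held 16161 regions and contained 89.3% of the pooled regions.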

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

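The tests of the looser list, of globin copies, of other tissues and of erythroid genes were chosen only after the results they bear on were seen. The test of the regions nearest Sfi1 names a gene known only from the results, so it also followed the sight of that gene's lead.

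The ranked lists held summits past the authors' threshold that the thresholded lists do not contain: 320 in the pooled list, 240 in replicate 1 and 230 in replicate 2. They came to light when each thresholded list was set against its ranked list, and they were not used in the results above. Of the 320, 126 lay off the main chromosomes, and the 320 formed 139 regions. Of the 84 regions on the main chromosomes, 47 had a copy elsewhere in the nuclear genome and 1 matched the mitochondrial genome. Several had folds above 26.7, the lowest among the 10 strongest distal regions named above. Examples are 49.6 (chromosome 9, 24541943 to 24542232) and 42.5 (chromosome 6, 103648978 to 103649356). The ranking by fold above therefore holds for the thresholded list only.

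The distal regions that lead by fold or by number included many with copies elsewhere. Among the 10 strongest, 5 matched the mitochondrial genome over at least 50% of their length, against 0 of 100 random distal regions, and 5 matched another nuclear place, against 3 of 100. The counts of 5 overlap, since the regions nearest G6pd2, Tyrp1, Galc and Nxph1 met both rules. The regions nearest Abcb11, Pak3, Frmd4a and Hic2 met neither, although 48.3% of the region nearest Abcb11 matched the mitochondrial genome. Reads of mitochondrial DNA placed on nuclear copies, and reads shared between nuclear copies, stay open for the 10 strongest as a set. In each test, 5 of 10 lay between the counts set for either outcome. For the 15 regions nearest Sfi1, reads shared with other nuclear copies may be the source, since 15 of 15 had a copy, although 8 had one on the main chromosomes, a count between those set, and the others on unplaced sequences only, a kind that the authors' ranked lists contain. No biological explanation was tested, since the design has 1 group.

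The replicate 1 list held 3539 regions that the replicate 2 list did not. Regions of replicate 1 without any signal in replicate 2 are argued against, since 85.4% of them (84.2 to 86.6) were in the looser list of replicate 2. A smaller number of regions past the threshold in replicate 2 accounts for part of the gap. Replicate 2 had 10751 regions against 13331, and nearly equal numbers were shared, 9851 and 9792, so part of the 3539 could have no partner. How far it goes beyond that was tested. Of the strongest 10751 regions of replicate 1 by −log10 p, as many as replicate 2 has, 85.4% (84.7 to 86.0) were in the replicate 2 list, and 83.0% when ranked by fold. The prediction was 85%, which the interval holds, so the count leaves the rest of the gap open, and the depth of the libraries is unknown. No biological explanation was tested.

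Blood and erythroid genes had promoter regions in hearts. A general opening of tissue-restricted promoters is argued against, since 6.90% (3.02 to 13.1) of 116 promoters in 6 lists of other tissues had one. Without the globin genes, a setting chosen after seeing the data and first written as a test of shared reads, the list stood at the 80.6 percentile for promoters and the 99.8 percentile for distal regions, but all 6 were open, so leaving them out had to lower the promoter value and decides nothing. Reads shared between near-identical globin genes stay open for Hba-a1 and Hba-a2: 2 of 6 globin promoters had a copy on the main assembly, and the further matches that made it 5 of 6 with alternate loci and patches lie on a contig of the same beta-globin locus from another strain. Cells of the blood in the dissected hearts are a candidate source that also stays open: 4 of 8 erythroid genes other than globins, among them Gata1 and Nfe2, had a region in both replicates, and 6 in the pooled list.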

How the results depend on the processing

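The setting that left out the globin genes was chosen only after the result was seen; all others were fixed before. Of 331 values under other settings, 252 gave the same call, 17 a weaker one and 21 a stronger one, 41 moved and 0 reversed. These calls are against the main setting, and the endothelial promoters, with no call there, went below the 5th percentile in some settings and above the 95th in another. Of 247 values for single consensus sequences, 204 gave the same call, 19 a weaker one, 21 a stronger one and 3 reversed. The cause of each change was not tested unless the setting itself shows it.

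With an overlap of 90% of the shorter region, 68.3% of replicate 1 regions and 85.3% of replicate 2 regions were shared, 59.3% of pooled regions were found in both and 5.13% in replicate 2 only. With an IDR of 0.01 in both lists the shared shares were 65.3% and 96.4%, and of pooled regions 49.0% were found in both, 25.3% in replicate 1 only, 1.72% in replicate 2 only and 24.0% in neither. In the looser lists they were 59.2% and 78.2%, with 51.6%, 22.6%, 8.84% and 17%. Counted as deposited, the pooled list held 36792 intervals instead of 16011 regions, since several summits share a region.

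With an IDR of 0.01, 74.7% of regions lay at promoters, and by summit 73.8% were promoter, 1.39% exon, 10.4% intron and 14.4% intergenic. The promoter percentiles were 21.2 for sarcomere, 0.810 for endothelium and 0.1 for epicardium. The distal percentiles were 88.9 for sarcomere, 93.2 for endothelium, 4.99 for neural and 91.7 for cell cycle genes, and 2 lists instead of 5 stood above the 95th percentile.

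In the looser replicated list, 38.0% of regions lay at promoters, and by summit 37.0% were promoter, 4.22% exon, 28.2% intron and 30.6% intergenic. Promoter percentiles were 99.92 for cardiac transcription factors, 98.6 for conduction, 99.5 for endothelium, 73.4 for the second heart field and 16.7 for neural genes, and 7 lists instead of 4 stood above the 95th. Distal percentiles were 99.3 for conduction and 98.5 for housekeeping genes. In the conservative list, promoter percentiles were 94.96 for sarcomere, 0.0150 for epicardium and 30.3 for the second heart field.

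With no matching of random lists, percentiles were 99.4 for cardiac transcription factor promoters, 89.2 for blood promoters, and for distal regions 99.5 for conduction, 3.74 for limb and 89.9 for cell cycle genes. With promoters of 2 kb, 1.53% of summits were exonic, and with 500 bp 2.43%, where the epicardial promoters stood at the 3.38 percentile. By the share of genes with a distal region, conduction stood at 96.1, housekeeping at 95.6 and cell cycle at 78.2. Within 50 kb, cell cycle stood at 93.6. Without globin genes, blood promoters stood at 80.6.

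Leaving out replicate 1 or replicate 2 gave, lowest to highest, promoter shares of 72.3% to 78.3%, and by summit 71.4% to 77.6% promoter, 1.18% to 1.47% exon, 8.48% to 11.7% intron and 12.7% to 15.4% intergenic. Promoter percentiles ran from 24.5 to 80.3 for sarcomere, 2.44 to 3.39 for endothelium, 0.0450 to 0.465 for epicardium and 0.805 to 8.18 for cushion genes. Distal percentiles ran from 94.5 to 99.2 for sarcomere, 84.9 to 99.7 for endothelium and 88.0 to 96.4 for housekeeping genes.

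Divided by the reversed consensus, the ratio was 7.46 for MEF2 at promoters, 1.70 for NKX2 at distal regions and 0.375 for the MYOD E-box at promoters, each on the other side of 1 from its ratio to the flanks. The SP and KLF consensus is the same sequence when reversed, so that setting says nothing for it. The reversed MYOD E-box was itself above its flanks at promoters, at 3.39, and holds a CG pair that the E-box lacks. Its turn at promoters therefore decides nothing. The depth of each library is unknown, so how far it sets the number of regions, and with it the shared shares and percentiles, could not be tested. No paired analysis was possible because there was 1 group.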

Other observations

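The 17 gene families given here were chosen after the main values were seen and are all those computed; the test of GATA sites was also settled after its result was seen.

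Families of genes that every growing cell uses had open promoters in the pooled list. Of the 80 ribosomal protein genes, 73 had a promoter region (91.3%, exact 95% interval 82.8 to 96.4). Of the 75 mitochondrial ribosomal protein genes 63 had one, of the 39 proteasome subunit genes 34 and of the 46 Nduf genes 41. The Nduf genes, taken by symbol, are subunits of NADH dehydrogenase, the entry complex of the respiratory chain, and its Ndufaf assembly factors. In matched random lists the means were 60.7%, 58.6%, 56.9% and 61.8%. Several large families mostly had no promoter region. Such a region was found for 1 of 329 vomeronasal receptor genes and 1 of 49 keratin genes (Krt8, which passed in neither replicate alone). It was also found for 1 of 57 clustered protocadherin genes (Pcdhgc3, with a fold of 8.18), 10 of 100 cytochrome P450 genes and 4 of 1134 olfactory receptor genes. Their matched means, in the same order, were 5.24%, 51.4%, 20.1%, 30.6% and 5.90%, and each of these families stood at percentile 0. The random lists could draw the families' own genes. The low matched means of both receptor families therefore do not show what GC content alone would give.

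Most of the other families had fewer open promoters than matched lists. Of the 15 Hox genes of groups 1 to 5, 1 had a promoter region, Hoxa1, with a fold of 5.53, which passed in neither replicate alone. Of the 24 Hox genes of groups 6 to 13 none had, against 63.6% in matched lists. Of the Wnt genes, which encode secreted growth signals, 2 of 19 had one, Wnt9a with 4.75 and Wnt2 with 4.14, against 74.1% in matched lists. The promoter of Wnt9a passed in replicate 1 and not in replicate 2, and that of Wnt2 in neither replicate alone. The Sox genes had 8 of 19, the forkhead genes 20 of 44, the collagen genes 9 of 44 and the potassium channel genes 15 of 81, among them Kcnj2 with 11.1, against 69.8%, 70.6%, 55.1% and 63.8% in matched lists. Of the 9 Notch receptors and ligands, 4 had one, Notch1, Notch2, Notch3 and Jag1, with folds of 6.02, 6.54, 4.32 and 4.78, against 69.8% in matched lists (percentile 6.08).

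The GATA sites at distal summits could be brought by blood cells alone, a hypothesis tested by the regions nearest to heart genes. Of the 49 distal regions nearest sarcomere and cardiac transcription factor genes, 6 had a GATA site (12.2%, 4.63 to 24.8), and of the 16 nearest blood genes 5 had one. The rule first written, that the lower limit lies at or under the share of the flanks, 5.57%, was met and would have favoured the hypothesis. The rule was changed after that was seen, because the same interval also holds the share over all distal regions, 17.6%, so 49 regions are too few to decide.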
